A study of Mus musculus with 9 samples.

How the data were processed

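RNA from 9 samples of RAW 264.7 cells, a mouse macrophage line, was sequenced after preparation with an Illumina total RNA kit that removes ribosomal RNA, starting from 300 ng of RNA. The labels give 1 batch for all 9 samples. Per the labels, reads were trimmed with Trimmomatic 0.36 and the genome build was GRCm38. DESeq is named there without a version or a role, and the aligner, the counting tool and the strandedness are not given in the sources used here. The control titles call the samples biological replicates, and the extraction notes describe RNA extracted in triplicate. Whether the samples of the other groups came from separate cultures is not given, so the tests measure the spread between these samples. The library names of the pamidronate + GGOH group carry a percentage tag that the labels do not explain.

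The deposited count table holds raw counts, whole numbers for 49315 genes, and was the starting point. The deposited per-sample files hold the same counts, with 0 rows differing from the table in each library. In the file of pamidronate + GGOH replicate 3, 26 gene symbols had been turned into spreadsheet dates, so symbols were taken from the combined table. The authors also deposited TPM values, which equal the count over the gene's exon length scaled to the same sum in each library, with a largest difference of 5e-05. The TPM values were not used in any test. Of the genes, 174 had no symbol in the files and 99.5% were found by identifier in GENCODE M21. All of those found lay on the same chromosome there, and 91.4% had the same start and end. Each pair of libraries in a group differed by more than counting error, with a chi-square per degree of freedom of 4.00 to 37.2, so no library was a copy of another.

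Samples were grouped by the treatment in their labels into control, pamidronate and pamidronate + GGOH, with 3 libraries each. The controls are labelled as untreated. The growth notes give RANKL for every sample, and the design text describes RANKL-treated cells with and without the bisphosphonate, so the controls were read as RANKL without pamidronate. Genes were kept with edgeR's filterByExpr at its defaults, which left 15963 genes, and libraries were scaled with TMM factors. All 9 libraries entered 1 model of group means, and each comparison was a contrast in edgeR's quasi-likelihood test (edgeR 4.0.16, robust fit, R 4.3.3) with Benjamini-Hochberg adjustment. A gene was called when its adjusted p was under 0.05, with no minimum fold change. The common dispersion was 0.0162, a biological coefficient of variation of 0.127, with 6 residual degrees of freedom and a median of 8.55 prior degrees of freedom. CPM values are counts scaled to library size with the TMM factors. The standard error (SE) of a fold change was derived as the absolute log2 fold change over the square root of the test's F statistic. Library totals ran from 14356069 to 18957968 counts. Intervals and floors cover counting error only. The floor was 3 counts over a group, and intervals for ratios to a group with 1 to 3 counts are at the 95% level.

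Before the data were examined, 27 gene lists, 6 marker lists of other cell types, the tests, the alternatives and the rule for named genes were fixed. The rule took the 8 highest and the 8 lowest called genes of each comparison with at least 5 CPM in the higher group and no overlap between groups, leaving out predicted and clone-named genes. It added up to 4 called members with the largest change from each list, and a fixed set of genes of isoprenoid synthesis, small GTPases, osteoclasts, inflammation and cell death. Of the lists, 25 are reported one by one, and not every gene that the rule took is named. Genes named outside the rule are marked as chosen after their values were seen. The lists were tested with camera from limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over 81 tests. The same test with an estimated correlation, and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, served as alternatives. Medians of the lists did not change when genes with 0 counts in a group were placed at their bound.

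The test was checked on simulated data with 15963 genes, of which 200 were changed between the control and pamidronate groups. It recovered 32% of genes changed 1.5-fold, 62% of those changed 2-fold and 92% of those changed 4-fold, with 5, 12 and 12 unchanged genes called. A simulated list raised 2-fold reached an adjusted p of 9.27e-99 with the preset and 1.25e-05 with an estimated correlation. Its genes were drawn independently of each other and no other gene was changed. It therefore does not show how often camera with an estimated correlation would find a changed list in these data. Alternatives were RLE and upper-quartile factors, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, fits of the 2 groups compared alone, a replicate block, an adjusted p under 0.01, a minimum absolute log2 fold change of 1, the per-sample files, and leaving out each library in turn. Leaving out the farthest control and pamidronate + GGOH libraries together, leaving out 2 genes that overlap ribosomal RNA sequence, upper-quartile factors for the genes outside both other groups, and dividing a shared group into 1 library and 2, were added after seeing the data. Replicate numbers did not pair the samples across all groups: correlations of residuals were -0.36 to 0.44 for libraries with the same number and -0.39 to 0.32 for those with different numbers. Between control and pamidronate + GGOH they were 0.44, -0.04 and 0.30 for replicates 1, 2 and 3. Between pamidronate and pamidronate + GGOH they were -0.22, 0.02 and -0.36. An effect of replicate number shared by control and pamidronate + GGOH libraries is therefore not excluded. Shares of counts and numbers of genes detected were compared with exact permutation tests, two-sided, for which 0.1 is the smallest p with 3 against 3. Figures were drawn with matplotlib 3.10.9.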

Results

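Gene expression was measured in RAW 264.7 cells, a mouse macrophage line that can form osteoclast-like cells when given RANKL, the cytokine that drives osteoclast formation. By the growth notes, the cells grew for 24 h before RANKL was added at 20 ng/ml. After a total of 48 h, 140 µM pamidronate was added with or without 5.25 µM geranylgeraniol (GGOH), and the cells were collected 24 h later. Pamidronate is a nitrogen-containing bisphosphonate that inhibits farnesyl diphosphate synthase, the product of Fdps. Its inhibition limits the isoprenoid lipids that anchor small GTPases in membranes. GGOH is the alcohol from which cells can make one of these lipids. The 3 groups were a control without pamidronate, pamidronate, and pamidronate + GGOH, with 3 libraries each.

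The control libraries held 18957968, 18911205 and 16943250 counts. The pamidronate libraries held 16644139, 16531586 and 16444207 counts, and the pamidronate + GGOH libraries held 16271462, 14356069 and 17559086. The number of genes detected was 21173 ± 1019 (SD, n = 3) in the control, 25080 ± 1347 (SD, n = 3) with pamidronate and 27077 ± 1624 (SD, n = 3) with pamidronate + GGOH. Both treated groups lay above the control (exact permutation p = 0.1, the smallest possible), and the treated groups overlapped each other (exact permutation p = 0.2). The first principal component held 68.9% of the variance and the second 16.5%. On the first, the pamidronate + GGOH libraries lay between the other groups, and replicate 3 of that group lay nearest the control. On the second, they lay outside both, at -52.3 to -42.7, while the control libraries lay at 15.1 to 19.4 and the pamidronate libraries at 25.3 to 34.0.

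**Figure D1:**
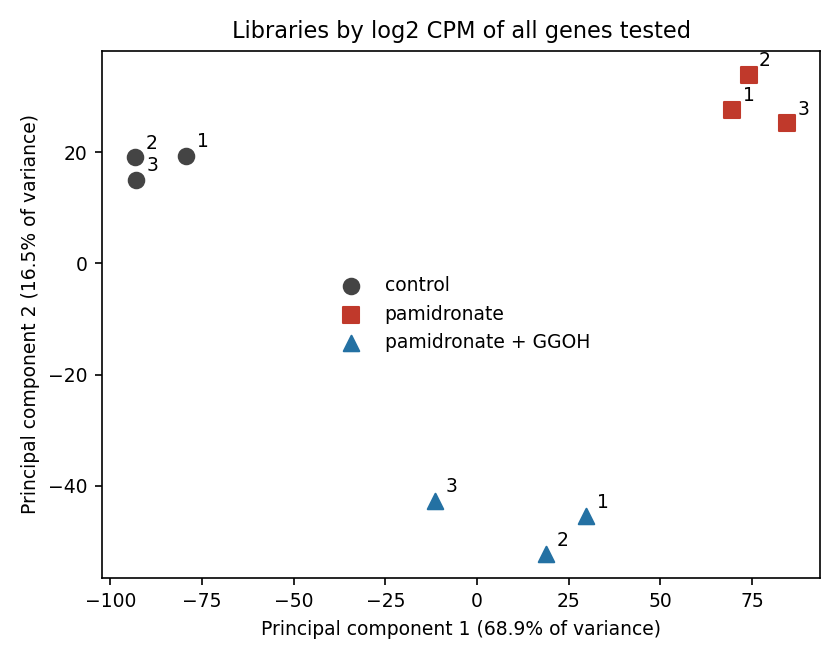
Position of the 9 libraries on the first and second principal components of log2 CPM over the genes tested; each point is a library with its replicate number. The control libraries sit between -93.3 and -79.3 on the first component, the pamidronate libraries between 69.6 and 84.6, and the pamidronate + GGOH libraries between -11.5 and 29.8, and on the second component the last group lies outside the other groups, at -52.3 to -42.7.

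The comparison of pamidronate with the control addressed how gene expression differed between cells given the bisphosphonate and cells without it. The controls are labelled as untreated while the growth notes give RANKL for every sample, so an effect of RANKL is not ruled out as part of this difference. Most genes in the list of sterol synthesis rose, 17 of 25, although this list did not pass with an estimated correlation (adjusted p = 0.514). Hmgcs1, an early enzyme of the mevalonate pathway (ENSMUSG00000093930, GRCm38 chromosome 13, 119690462 to 119708086), rose from 35.5 ± 7.39 (SD, n = 3) to 196 ± 19.5 (SD, n = 3) CPM, a log2 fold change of 2.46 ± 0.14 (SE) with an adjusted p of 1.43e-08 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 23 macrophage markers, 21 fell, and this list did not pass with an estimated correlation either (adjusted p = 0.4). Csf1r, the receptor for the macrophage growth factor (ENSMUSG00000024621, chromosome 18, 61105572 to 61132149), fell from 1391 ± 30.7 (SD, n = 3) to 98.5 ± 22.4 (SD, n = 3) CPM, a log2 fold change of -3.82 ± 0.30 (SE, adjusted p = 4.59e-06). Of 15963 genes tested, 11042 were called, 5784 higher and 5258 lower with pamidronate. Of these, 6047 differed at least 2-fold. For every gene named below as higher or lower with pamidronate, the 3 libraries of one group lay apart from the 3 of the other, which held for 73.4% of all genes tested and holds for 10% by chance.

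Of the 25 genes in the list of mevalonate and cholesterol synthesis, 17 rose and 3 fell with pamidronate, and 20 were called when adjusted over the list alone. The median log2 fold change of the list was 0.75 (camera adjusted p = 0.00257, adjusted p = 0.514 with an estimated correlation). Insig1, which holds back sterol synthesis when sterols are plentiful (ENSMUSG00000045294, chromosome 5, 28071363 to 28078662), rose by 3.94 ± 0.29 (SE) on the log2 scale. Fdps rose by 0.75 ± 0.17 (SE, adjusted p = 0.00147). Ggps1, which makes geranylgeranyl diphosphate and overlaps Arid4b on the other strand, rose by 0.37 ± 0.10 (SE, adjusted p = 0.00311), a call lost with no filter on low counts (adjusted p = 0.072). In the list of the isoprenoid branch and prenylation enzymes, 5 of 20 genes rose and 10 fell (15 adjusted over the list alone, camera adjusted p = 0.403), and with upper-quartile factors 9 rose and 8 fell. Coq2, an enzyme of ubiquinone synthesis, fell from 14.7 ± 1.04 (SD, n = 3) to 2.81 ± 0.449 (SD, n = 3) CPM.

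The small GTPases moved in both directions. Rhoa (ENSMUSG00000007815, chromosome 9, 108306129 to 108337934) fell from 595 ± 22.4 (SD, n = 3) to 323 ± 37.4 (SD, n = 3) CPM, with a log2 fold change of -0.88 ± 0.12 (SE). Cdc42 (ENSMUSG00000006699, chromosome 4, 137319696 to 137357720), Rac1 (ENSMUSG00000001847, chromosome 5, 143503634 to 143528036) and Rac2 (ENSMUSG00000033220, chromosome 15, 78559169 to 78572783) changed by -1.39 ± 0.12, -1.27 ± 0.11 and -1.17 ± 0.10 (SE). Rhob (ENSMUSG00000054364, chromosome 12, 8497763 to 8499985) rose by 1.29 ± 0.11 (SE). Of 45 Rab genes, 11 rose and 24 fell (35 adjusted over the list alone, median -0.26, camera adjusted p = 0.027, adjusted p = 0.4 with an estimated correlation), among them Rab7, a regulator of late endosomes, at -0.86 ± 0.10 (SE), and with upper-quartile factors 12 rose and 19 fell, with a median of -0.07. Of 24 Ras genes, 7 rose and 11 fell (18 adjusted over the list alone, camera adjusted p = 0.315), and with upper-quartile factors 9 rose and 10 fell. Of 27 Arf genes, which are not prenylated, 9 rose and 12 fell (21 adjusted over the list alone, camera adjusted p = 0.461), and with upper-quartile factors 11 rose and 10 fell. Rap1a fell by 0.91 on the log2 scale, and Arf4 rose by 2.15 ± 0.11 (SE). Of 26 heterotrimeric G protein subunits, 9 rose and 13 fell (22 adjusted over the list alone, camera adjusted p = 0.403), with Gng8 4.52 ± 0.28 (SE) higher. In the Ras and heterotrimeric lists, the medians were -0.18 and -0.20 while the means were 0.14 and 0.36, camera gave both as lower, and with upper-quartile factors the Ras median was 0.01.

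Genes of adhesion and the cytoskeleton mostly fell. Of 36 podosome and adhesion genes, 3 rose and 29 fell (33 adjusted over the list alone, median -1.13, camera adjusted p = 7.23e-08, adjusted p = 0.4 with an estimated correlation). Itga4, an integrin subunit (ENSMUSG00000027009, chromosome 2, 79255426 to 79333123), fell from 4995 ± 244 (SD, n = 3) to 631 ± 139 (SD, n = 3) CPM, and Gsn, the actin-severing protein gelsolin, changed by -2.65 ± 0.13 (SE) on the log2 scale. Of 26 genes of the actin cytoskeleton and of SRF and YAP targets, 5 rose and 19 fell (24 adjusted over the list alone, median -0.89, camera adjusted p = 0.00202, adjusted p = 0.4 with an estimated correlation), with Actb, cytoplasmic actin, at -2.32 ± 0.18 (SE).

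Of 23 macrophage markers, 1 rose and 21 fell (22 adjusted over the list alone, median -2.69, camera adjusted p = 7.23e-08, adjusted p = 0.4 with an estimated correlation). Cx3cr1, a chemokine receptor, changed by -4.35 ± 0.46 (SE) on the log2 scale. Of 32 osteoclast genes, 10 rose and 16 fell (26 adjusted over the list alone, camera adjusted p = 0.269), and with upper-quartile factors 14 rose and 14 fell. Ctsk, the main collagen-degrading protease of osteoclasts (ENSMUSG00000028111, chromosome 3, 95499256 to 95509362), rose from 4.70 ± 1.61 (SD, n = 3) to 32.9 ± 3.04 (SD, n = 3) CPM. Car2, the carbonic anhydrase used for acid secretion, changed by -2.71 ± 0.23 (SE), and Nfatc1, the main osteoclast transcription factor, by -0.66 ± 0.08 (SE). Mmp9 was not called (adjusted p = 0.185), but was called lower without pamidronate + GGOH replicate 3 (adjusted p = 0.0469). Acp5 was not called either (adjusted p = 0.0969), but was called higher with upper-quartile factors (adjusted p = 0.0253) and without control replicate 1 (adjusted p = 0.0156). Of 41 lysosomal genes, 11 rose and 21 fell (32 adjusted over the list alone, camera adjusted p = 0.12), and with upper-quartile factors 18 rose and 17 fell.

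Stress genes were among the called genes that rose. Gdf15 and Plk2, both p53 targets, rose by 4.20 ± 0.14 and 4.41 ± 0.17 (SE) on the log2 scale, and Cdkn1a, the cell cycle inhibitor p21, by 1.13 ± 0.11 (SE). Of 24 p53 targets, 11 rose and 8 fell (19 adjusted over the list alone, camera adjusted p = 0.209). Atf4 and Atf3, transcription factors of the integrated stress response, rose by 2.41 ± 0.14 and 2.39 ± 0.13 (SE). In that list of 31 genes, 11 rose and 11 fell (22 adjusted over the list alone, camera adjusted p = 0.653), and with upper-quartile factors 17 rose and 9 fell. Of 31 inflammatory genes, 18 rose and 8 fell (27 adjusted over the list alone, median 1.72, camera adjusted p = 0.0655), with Ccl5, a chemokine, 3.87 ± 0.31 (SE) higher and Nlrp3, an inflammasome sensor, at -3.70 ± 0.18 (SE). This list passed when control replicate 2 or 3, pamidronate replicate 2 or 3, or pamidronate + GGOH replicate 1 or 2 was left out (adjusted p = 0.0367 to 0.0491). It did not pass in camera with an estimated correlation (adjusted p = 0.4). Of 30 interferon response genes, 12 rose and 8 fell (19 adjusted over the list alone, camera adjusted p = 0.595), with Rsad2, an antiviral enzyme, at 4.62 ± 0.33 (SE). Of 25 oxidative stress genes, 6 rose and 13 fell (19 adjusted over the list alone, camera adjusted p = 0.12), with Hmox1, haem oxygenase, at 2.10 ± 0.18 (SE). Of 29 autophagy genes, 17 rose and 6 fell (23 adjusted over the list alone, camera adjusted p = 0.0545), and the list passed without control replicate 1 (adjusted p = 0.0404), without pamidronate replicate 3 (adjusted p = 0.0466) and with a stricter filter (adjusted p = 0.0467). The autophagy list did not pass in camera with an estimated correlation (adjusted p = 0.514). Nbr1, an autophagy receptor, rose by 1.61 ± 0.14 (SE).

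Of 35 apoptosis genes, 8 rose and 21 fell (29 adjusted over the list alone, median -0.50, camera adjusted p = 0.0113, adjusted p = 0.4 with an estimated correlation), and with upper-quartile factors 9 rose and 19 fell, with a median of -0.31. Bmf, which promotes apoptosis, changed by -3.65 ± 0.18 (SE) on the log2 scale, and Bcl2l11, also pro-apoptotic, by 0.55 ± 0.10 (SE). Of 40 DNA replication genes, 3 rose and 25 fell (28 adjusted over the list alone, median -0.82, camera adjusted p = 0.0107, adjusted p = 0.733 with an estimated correlation), with Prim1, a primase subunit, at -1.90 ± 0.28 (SE). Of 40 mitosis genes, 2 rose and 12 fell (2 adjusted over the list alone, median -1.06, camera adjusted p = 0.0417, adjusted p = 0.81 with an estimated correlation). The mitosis call was lost without control replicate 2 (adjusted p = 0.124), control replicate 3 (0.282) or pamidronate replicate 3 (0.0646), with RLE factors (0.0506) and with a stricter filter (0.0682). Of 24 replication-dependent histone genes, whose RNAs carry no poly(A) tail, 2 rose and 15 fell (17 adjusted over the list alone, median -1.45, camera adjusted p = 0.037, adjusted p = 0.733 with an estimated correlation). That call was lost without control replicate 2 (adjusted p = 0.0627), control replicate 3 (0.0802) or pamidronate replicate 1 (0.0564) and with a stricter filter (0.0564). With fry, the replication, mitosis and histone lists were not called (adjusted p = 0.126, 0.353 and 0.188). The control libraries differed among themselves here, with histone RNAs at 0.0371%, 0.0744% and 0.101% of counts in replicates 1, 2 and 3.

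Mitochondrially encoded transcripts and most nuclear genes of oxidative phosphorylation fell as well. Of 12 mitochondrially encoded transcripts, all 12 fell (12 adjusted over the list alone, median -1.74, camera adjusted p = 1.9e-05, adjusted p = 0.4 with an estimated correlation), with mt-Cytb at -2.67 ± 0.25 (SE). Among them, mt-Co2, mt-Atp6, mt-Co3, mt-Nd4l and mt-Atp8 had low counts, at 3.04 to 6.30 CPM in the control, while mt-Co1 had 62092 CPM. The low-count transcripts enter this list in every comparison, but the mitochondrial share of counts rests on the others. Mitochondrial RNA made up 10.5% ± 0.231 (SD, n = 3) of counts in the control and 4.20% ± 0.848 (SD, n = 3) with pamidronate (exact permutation p = 0.1, the smallest possible). Malat1, a nuclear RNA named after its values were seen, made up 1.52% ± 0.159 (SD, n = 3) and 4.83% ± 0.263 (SD, n = 3) of counts in these groups. Gm26917, which overlaps ribosomal RNA sequence and was also named after its values were seen, made up 7.70% ± 0.641 (SD, n = 3) and 12.4% ± 0.421 (SD, n = 3), and 10.8% ± 0.848 (SD, n = 3) with pamidronate + GGOH. Of 41 nuclear genes of oxidative phosphorylation, 1 rose and 27 fell (28 adjusted over the list alone, median -0.45, camera adjusted p = 0.00014, adjusted p = 0.449 with an estimated correlation), with Sdha at -1.41 ± 0.12 (SE), and with upper-quartile factors 4 rose and 20 fell, with a median of -0.25. Of 22 LXR targets and fatty acid synthesis genes, 1 rose and 15 fell (16 adjusted over the list alone, median -0.54, camera adjusted p = 0.00172, adjusted p = 0.4 with an estimated correlation), with Abca1, the cholesterol exporter, at -2.11 ± 0.44 (SE), and with upper-quartile factors 3 rose and 12 fell, with a median of -0.35. Of 31 glycolysis and hypoxia genes, 8 rose and 15 fell (23 adjusted over the list alone, camera adjusted p = 0.0899), with upper-quartile factors 10 rose and 12 fell, and the list passed without control replicate 3 (adjusted p = 0.0316). It did not pass in camera with an estimated correlation (adjusted p = 0.703). Pdk1, which limits pyruvate use in mitochondria, changed by -2.59 ± 0.11 (SE).

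The genes with the highest log2 fold changes under the fixed rule were nearly silent in the control. Dio2, a thyroid hormone deiodinase (ENSMUSG00000007682, chromosome 12, 90724554 to 90738438), rose from 0.487 ± 0.0657 (SD, n = 3) to 105 ± 8.89 (SD, n = 3) CPM. Fam71f2 reached 240.2 ± 41.1 (SD, n = 3) CPM from 1.21 ± 0.631 (SD, n = 3), and Eqtn 46.9 ± 5.99 (SD, n = 3) CPM from 0.216 ± 0.0368 (SD, n = 3). Cckar, a cholecystokinin receptor, had 1 count over the control group and was 1063-fold higher with pamidronate, with a counting interval of 190.3 to 42024. Among the genes that fell most were Sla, an adaptor that restrains receptor signalling, at -6.50 ± 0.53 (SE), Selenop, a secreted selenoprotein, at -6.38 ± 0.46 (SE), and Mrc1, the mannose receptor, at -6.25 ± 0.58 (SE).

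**Figure D2:**
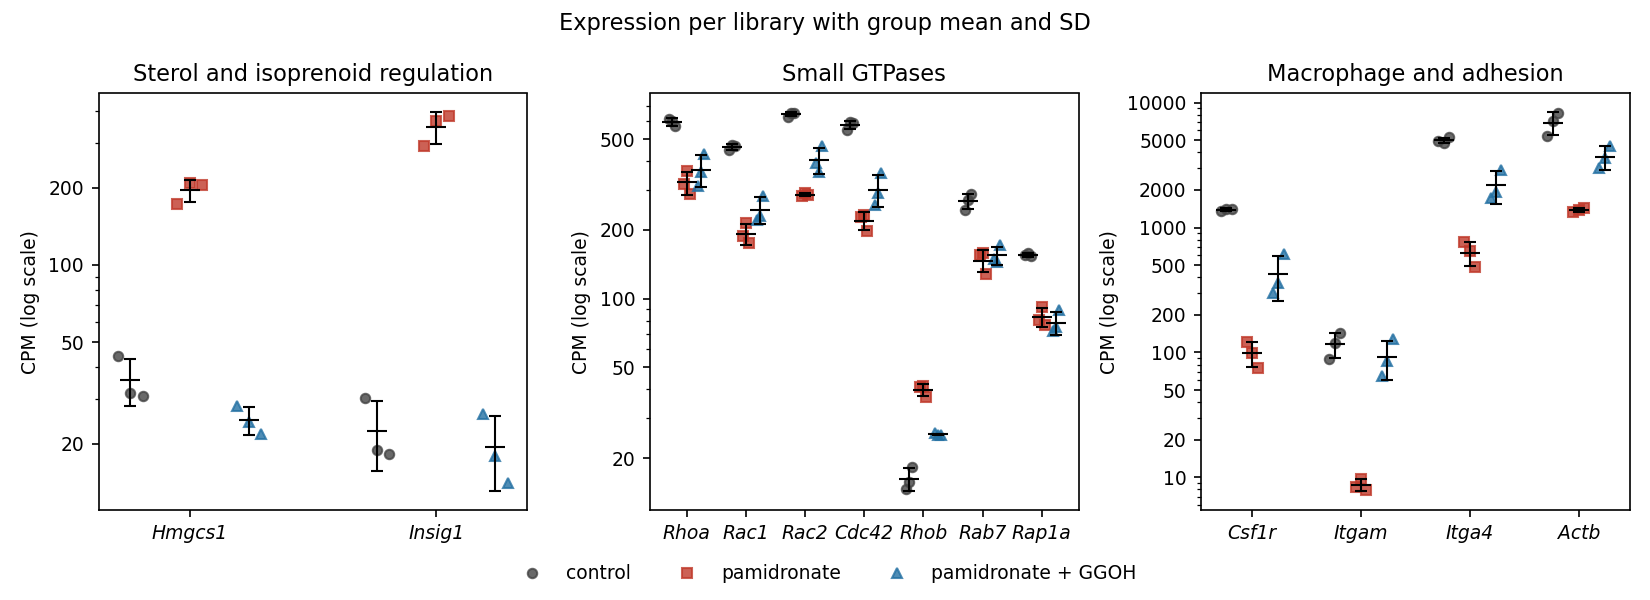
CPM of sterol, small GTPase, macrophage and adhesion genes on log axes; each point is a library, and the bars give the group mean and SD (n = 3). Hmgcs1 averaged 35.5, 196 and 24.8 CPM in the control, pamidronate and pamidronate + GGOH groups, and Csf1r averaged 1391, 98.5 and 424 CPM.

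The comparison of pamidronate + GGOH with pamidronate addressed what GGOH changed in pamidronate-treated cells. With GGOH, 19 of 25 sterol synthesis genes were lower, and 17 of 23 macrophage markers and 27 of 36 adhesion genes were higher. None of these 3 lists passed with an estimated correlation (adjusted p = 0.4, 0.477 and 0.449). Hmgcs1 fell from 196 ± 19.5 (SD, n = 3) to 24.8 ± 3.20 (SD, n = 3) CPM, a log2 fold change of -2.98 ± 0.15 (SE, adjusted p = 3.27e-08). Csf1r rose from 98.5 ± 22.4 (SD, n = 3) to 424 ± 168 (SD, n = 3) CPM, a log2 fold change of 2.11 ± 0.28 (SE, adjusted p = 0.000314). Of 15963 genes, 7784 were called, 4022 higher and 3762 lower with GGOH, and 2590 of them differed at least 2-fold. For every gene named below as changed by GGOH, the libraries of the groups lay apart, which held for 59.6% of all genes tested and holds for 10% by chance.

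Of the 25 mevalonate and cholesterol synthesis genes, 1 rose and 19 fell with GGOH (23 adjusted over the list alone, median -1.66, camera adjusted p = 3.47e-09, adjusted p = 0.4 with an estimated correlation). Insig1 and Fdps changed by -4.16 ± 0.29 and -1.73 ± 0.18 (SE) on the log2 scale. Ggps1 was not called (adjusted p = 0.105). Of 20 isoprenoid branch genes, 7 rose and 5 fell (12 adjusted over the list alone, camera adjusted p = 0.529), with Coq2 at 1.88 ± 0.17 (SE). Of 22 LXR targets and fatty acid synthesis genes, 3 rose and 11 fell (14 adjusted over the list alone, camera adjusted p = 0.166), and this list passed without pamidronate + GGOH replicate 3 (adjusted p = 0.0303). It did not pass in camera with an estimated correlation (adjusted p = 0.629). Scd1, a fatty acid desaturase, changed by -1.79 ± 0.16 (SE).

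The small GTPases moved both ways. Rac2 and Cdc42 rose by 0.51 ± 0.10 and 0.45 ± 0.11 (SE) on the log2 scale. Rac1 rose by 0.35 ± 0.11 (SE, adjusted p = 0.0141), a call lost without pamidronate replicate 1 or 3 (adjusted p up to 0.0784). Rhoa, at 367 ± 59.4 (SD, n = 3) CPM, was not called (log2 fold change 0.18 ± 0.12 (SE), adjusted p = 0.212), except when pamidronate + GGOH replicate 1 was left out, where it reached 0.34 (adjusted p = 0.0298). Rhob, which pamidronate had raised, fell by 0.64 on the log2 scale. Of 24 Ras genes, 6 rose and 7 fell (15 adjusted over the list alone, camera adjusted p = 0.917), and of 45 Rab genes, 16 rose and 10 fell (27 adjusted over the list alone, camera adjusted p = 0.917). Of 27 Arf genes, 6 rose and 10 fell (16 adjusted over the list alone, camera adjusted p = 0.253), and of 26 heterotrimeric subunits, 9 rose and 7 fell (16 adjusted over the list alone, camera adjusted p = 0.959). Arf4 changed by -2.22 ± 0.11 (SE), and Gna15, a G protein alpha subunit of blood cells, by 1.73 ± 0.26 (SE). Rap1a (adjusted p = 0.521) and Rab7 (adjusted p = 0.559) were not called. Medians and means differed in sign for the Rab list (-0.04 and 0.10) and the heterotrimeric list (0.04 and -0.03). They also did so for the osteoclast list (-0.01 and 0.18, with a median of 0.00 under upper-quartile factors) and the lysosomal list (-0.09 and 0.02), and none of these 4 lists was called.

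Of 36 podosome and adhesion genes, 27 rose and 2 fell with GGOH (31 adjusted over the list alone, median 0.54, camera adjusted p = 1.66e-05, adjusted p = 0.449 with an estimated correlation), with Itga4 at 1.79 ± 0.20 (SE). Of 26 actin cytoskeleton genes, 15 rose and 2 fell (18 adjusted over the list alone, median 0.51, camera adjusted p = 0.00903, adjusted p = 0.4 with an estimated correlation), with Actb at 1.42 ± 0.17 (SE). Of 23 macrophage markers, 17 rose and 2 fell (21 adjusted over the list alone, median 1.49, camera adjusted p = 2.05e-05, adjusted p = 0.477 with an estimated correlation), with Itgam, an integrin subunit of myeloid cells, at 3.40 ± 0.30 (SE). Of 32 osteoclast genes, 12 rose and 8 fell (20 adjusted over the list alone, camera adjusted p = 0.653). Mmp9, a matrix protease, and Car2 rose by 2.30 ± 0.38 and 2.23 ± 0.23 (SE), Ctsk and Acp5 fell by 1.61 and 1.10 on the log2 scale, and Nfatc1 was not called (adjusted p = 0.646). Of 41 lysosomal genes, 12 rose and 14 fell (27 adjusted over the list alone, camera adjusted p = 0.694).

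Of 24 p53 targets, 3 rose and 16 fell with GGOH (19 adjusted over the list alone, median -0.59, camera adjusted p = 7.42e-05, adjusted p = 0.4 with an estimated correlation), with Gdf15 at -2.20 ± 0.12 (SE) and Cdkn1a at -1.24 ± 0.11 (SE). Of 29 autophagy genes, 6 rose and 16 fell (24 adjusted over the list alone, median -0.40, camera adjusted p = 0.00207, adjusted p = 0.4 with an estimated correlation), with Ulk1, the kinase that starts autophagy, at -1.59 ± 0.08 (SE). Of 35 apoptosis genes, 18 rose and 6 fell (24 adjusted over the list alone, median 0.32, camera adjusted p = 0.0401, adjusted p = 0.4 with an estimated correlation), a call lost without pamidronate replicate 3 (adjusted p = 0.0505) or pamidronate + GGOH replicate 3 (0.0865). Bmf rose by 1.74 ± 0.18 (SE). Of 30 interferon response genes, 17 rose and 4 fell (23 adjusted over the list alone, median 0.82, camera adjusted p = 0.0113, adjusted p = 0.611 with an estimated correlation), with Oasl2 at 1.95 ± 0.34 (SE). Of 25 oxidative stress genes, 12 rose and 3 fell (16 adjusted over the list alone, median 0.38, camera adjusted p = 0.0116, adjusted p = 0.611 with an estimated correlation), with Srxn1, which repairs peroxiredoxins, at 1.73 ± 0.17 (SE). Of 31 inflammatory genes, 6 rose and 7 fell (13 adjusted over the list alone, camera adjusted p = 0.756), with Nlrp3 at 3.03 ± 0.18 (SE). Of 31 integrated stress response genes, 10 rose and 10 fell (23 adjusted over the list alone, camera adjusted p = 0.758), with Atf4 at -1.29 ± 0.14 (SE).

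Of 31 glycolysis and hypoxia genes, 14 rose and 4 fell (19 adjusted over the list alone, median 0.34, camera adjusted p = 0.00371, adjusted p = 0.514 with an estimated correlation), with Pdk1 at 1.91 ± 0.10 (SE). Of 12 mitochondrially encoded transcripts, 7 rose and 0 fell (7 adjusted over the list alone, median 0.55, camera adjusted p = 0.00368, adjusted p = 0.514 with an estimated correlation), with mt-Cytb at 1.37 ± 0.24 (SE). The mitochondrial share of counts was 5.96% ± 0.481 (SD, n = 3) with GGOH and 4.20% ± 0.848 (SD, n = 3) without (exact permutation p = 0.1, the smallest possible). Of 41 oxidative phosphorylation genes, 6 rose and 7 fell (13 adjusted over the list alone, camera adjusted p = 0.847). Of 40 DNA replication genes, 1 rose and 7 fell (8 adjusted over the list alone, median 0.22, camera adjusted p = 0.911 in the lower direction). Of 40 mitosis genes, 0 rose and 2 fell (2 adjusted over the list alone, camera adjusted p = 0.529), and this list passed without pamidronate + GGOH replicate 3 (adjusted p = 0.0416). It did not pass in camera with an estimated correlation (adjusted p = 0.957). Of 24 histone genes, 0 rose and 3 fell (2 adjusted over the list alone, median 0.20, camera adjusted p = 0.756 in the lower direction). The highest log2 fold changes under the rule included Mgl2, a macrophage lectin, at 6.81 ± 0.96 (SE), Siglec1, a macrophage surface receptor, at 5.76 ± 0.52 (SE), and Ptgs1, cyclooxygenase-1, at 5.01 ± 0.28 (SE). Siglec1 rose from 5.02 ± 0.966 (SD, n = 3) to 273 ± 134 (SD, n = 3) CPM. The lowest, beside sterol genes, included Eps8l1, an actin regulator, at -3.93 ± 0.34 (SE), and Myc, which drives cell growth, at -2.61 ± 0.33 (SE).

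The comparison of pamidronate + GGOH with the control addressed how far cells given both compounds stood from the control. Of 23 macrophage markers, 17 were lower than in the control, as were 28 of 36 adhesion genes, 12 of 12 mitochondrially encoded transcripts and 17 of 25 sterol synthesis genes, and 17 of 30 interferon response genes were higher. None of these 5 lists passed with an estimated correlation (adjusted p = 0.477 for the interferon list and 0.4 for the others). Csf1r remained at 424 ± 168 (SD, n = 3) against 1391 ± 30.7 (SD, n = 3) CPM, a log2 fold change of -1.71 ± 0.27 (SE, adjusted p = 0.000909). Fdps stood at 5.95 ± 1.27 (SD, n = 3) against 11.7 ± 2.59 (SD, n = 3) CPM, a log2 fold change of -0.98 ± 0.18 (SE, adjusted p = 0.000546). Of 15963 genes, 8359 were called, 4202 higher and 4157 lower than in the control. At least 2-fold differences were found for 3079, with 2432 higher and 647 lower. With upper-quartile factors, which moved the median of all genes by 0.201 on the log2 scale, 5834 were higher and 2600 lower. The same factors moved the median by 0.194 for pamidronate against the control, where 7003 were higher and 4317 lower. The groups lay apart for 58.2% of all genes tested, against 10% by chance, and for each gene named below as changed.

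Of the 25 mevalonate and cholesterol synthesis genes, 0 were higher and 17 lower than in the control (18 adjusted over the list alone, median -0.64, camera adjusted p = 4.48e-05, adjusted p = 0.4 with an estimated correlation). Idi1, which makes isoprenoid building blocks, stood at -1.17 ± 0.18 (SE) on the log2 scale. Hmgcs1 stood at -0.52 ± 0.14 (SE, adjusted p = 0.00833), a call lost with upper-quartile factors (adjusted p = 0.0993), and without control replicate 1 and pamidronate + GGOH replicate 3 together, where it was -0.26 (adjusted p = 0.0541). Of 20 isoprenoid branch genes, 4 were higher and 8 lower (12 adjusted over the list alone, camera adjusted p = 0.385), and with upper-quartile factors 7 were higher and 4 lower. Of 22 LXR targets and fatty acid synthesis genes, 2 were higher and 16 lower (20 adjusted over the list alone, median -0.78, camera adjusted p = 3.88e-06, adjusted p = 0.4 with an estimated correlation), with Abca1 at -3.22 ± 0.46 (SE) and Scd1 at -2.17 ± 0.16 (SE).

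Against the control, Rhoa, Rac1, Rac2 and Cdc42 stood at -0.70 ± 0.12, -0.92 ± 0.11, -0.66 ± 0.10 and -0.94 ± 0.11 (SE) on the log2 scale, and Rhob at 0.65 ± 0.11 (SE). Of 45 Rab genes, 3 were higher and 22 lower (25 adjusted over the list alone, median -0.33, camera adjusted p = 0.000299, adjusted p = 0.4 with an estimated correlation), with Rab7 at -0.79 ± 0.10 (SE) and Rab10 at -1.29 ± 0.14 (SE), and with upper-quartile factors 4 were higher and 16 lower, with a median of -0.12. Of 27 Arf genes, 1 was higher and 11 lower (12 adjusted over the list alone, median -0.25, camera adjusted p = 0.00414, adjusted p = 0.4 with an estimated correlation), and with upper-quartile factors 2 were higher and 9 lower, with a median of -0.04. Of 24 Ras genes, 4 were higher and 11 lower (15 adjusted over the list alone, median -0.40, mean 0.05, camera adjusted p = 0.113), and with upper-quartile factors 8 were higher and 8 lower. Of 26 heterotrimeric subunits, 7 were higher and 13 lower (20 adjusted over the list alone, median -0.24, mean 0.33, camera adjusted p = 0.189), and with upper-quartile factors 9 were higher and 10 lower. Of 36 podosome and adhesion genes, 5 were higher and 28 lower (34 adjusted over the list alone, median -0.59, camera adjusted p = 6.06e-07, adjusted p = 0.4 with an estimated correlation), with Gsn at -1.37 ± 0.12 (SE), and with upper-quartile factors 5 were higher and 22 lower, with a median of -0.39. Of 26 actin cytoskeleton genes, 2 were higher and 15 lower (18 adjusted over the list alone, median -0.49, camera adjusted p = 0.0183, adjusted p = 0.4 with an estimated correlation), with Tpm4, a tropomyosin, at -1.06 ± 0.13 (SE), and with upper-quartile factors 6 were higher and 11 lower, with a median of -0.29.

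Of 23 macrophage markers, 0 were higher and 17 lower than in the control (17 adjusted over the list alone, median -1.22, camera adjusted p = 7.23e-08, adjusted p = 0.4 with an estimated correlation). Of 32 osteoclast genes, 11 were higher and 14 lower (27 adjusted over the list alone, camera adjusted p = 0.185). Itgb3, the integrin subunit of osteoclast attachment, rose from 1.53 ± 0.435 (SD, n = 3) to 11.7 ± 1.54 (SD, n = 3) CPM, Mmp9 stood at 1.68 ± 0.36 (SE) on the log2 scale, Ctsk at 1.20 ± 0.22 (SE) and Nfatc1 at -0.72 ± 0.08 (SE). Of 41 lysosomal genes, 6 were higher and 20 lower (26 adjusted over the list alone, median -0.23, camera adjusted p = 0.0109, adjusted p = 0.477 with an estimated correlation), with Ctss, a lysosomal protease, at -1.12 ± 0.13 (SE), and with upper-quartile factors 13 were higher and 17 lower, with a median of -0.03. Of 41 oxidative phosphorylation genes, 0 were higher and 30 lower (32 adjusted over the list alone, median -0.41, camera adjusted p = 6.06e-07, adjusted p = 0.4 with an estimated correlation), and with upper-quartile factors 2 were higher and 17 lower, with a median of -0.21. All 12 mitochondrially encoded transcripts were lower (12 adjusted over the list alone, median -1.09, camera adjusted p = 1.66e-05, adjusted p = 0.4 with an estimated correlation), with mt-Nd4 at -1.48 ± 0.18 (SE).

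Of 30 interferon response genes, 17 were higher and 0 lower than in the control (17 adjusted over the list alone, median 0.77, camera adjusted p = 7.42e-05, adjusted p = 0.477 with an estimated correlation), with Rsad2 at 3.27 ± 0.33 (SE) and Oasl2 at 2.70 ± 0.36 (SE). Of 31 inflammatory genes, 16 were higher and 7 lower (24 adjusted over the list alone, median 0.86, camera adjusted p = 0.0109, adjusted p = 0.4 with an estimated correlation), with Il1rn, the antagonist of the interleukin-1 receptor, at 3.49 ± 0.22 (SE). Of 40 DNA replication genes, 0 were higher and 19 lower (18 adjusted over the list alone, median -0.82, camera adjusted p = 6.17e-05, adjusted p = 0.611 with an estimated correlation), and with upper-quartile factors 0 were higher and 9 lower. Of 40 mitosis genes, 0 were higher and 6 lower (1 adjusted over the list alone, median -1.08, camera adjusted p = 0.000736, adjusted p = 0.692 with an estimated correlation), and of 24 histone genes, 1 was higher and 12 lower (16 adjusted over the list alone, median -1.23, camera adjusted p = 0.00172, adjusted p = 0.611 with an estimated correlation). With upper-quartile factors, 4 mitosis genes and 8 histone genes were lower. With fry, the replication, mitosis and histone lists were not called (adjusted p = 0.0827, 0.194 and 0.0926). Of 24 p53 targets, 4 were higher and 12 lower (16 adjusted over the list alone, camera adjusted p = 0.0655), with upper-quartile factors 4 were higher and 7 lower, and Plk2 stood at 3.77 ± 0.17 (SE). The p53 list passed without control replicate 1 or 3 or pamidronate replicate 2 or 3 (adjusted p = 0.0299 to 0.0492), but not in camera with an estimated correlation (adjusted p = 0.514).

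Of 35 apoptosis genes, 4 were higher and 12 lower than in the control (16 adjusted over the list alone, camera adjusted p = 0.0517), and with upper-quartile factors 8 were higher and 10 lower. The apoptosis list passed with RLE factors (adjusted p = 0.0472), with a replicate block (adjusted p = 0.0464) and when any library but control replicate 2 or pamidronate + GGOH replicate 1 was left out (adjusted p = 0.0227 to 0.0436). It did not pass in camera with an estimated correlation (adjusted p = 0.4). Of 31 integrated stress response genes, 10 were higher and 9 lower (19 adjusted over the list alone, median -0.06, mean 0.18, camera adjusted p = 0.572 in the higher direction), and with upper-quartile factors 11 were higher and 6 lower, with Atf3 at 1.42 ± 0.13 (SE). Of 25 oxidative stress genes, 5 were higher and 9 lower (14 adjusted over the list alone, median -0.06, mean 0.10, camera adjusted p = 0.978), and with upper-quartile factors 7 were higher and 5 lower. Of 29 autophagy genes, 6 were higher and 7 lower (13 adjusted over the list alone, median -0.08, mean 0.11, camera adjusted p = 0.817), and with upper-quartile factors 9 were higher and 4 lower. Hmox1 stood at 2.22 ± 0.18 (SE), and Sqstm1, an autophagy receptor, at 1.31 ± 0.13 (SE). Of 31 glycolysis and hypoxia genes, 11 were higher and 7 lower (18 adjusted over the list alone, camera adjusted p = 0.599), with Slc2a1, a glucose transporter, at 1.45 ± 0.12 (SE). Among the highest log2 fold changes, Pappa2, a protease that releases insulin-like growth factor, had 0 control counts and was at least 121-fold higher, and Efcab6 rose from 0.139 ± 0.0720 (SD, n = 3) to 62.5 ± 23.3 (SD, n = 3) CPM. Among the lowest were Selenop at -3.98 ± 0.37 (SE) and Maf, a macrophage transcription factor, at -3.25 ± 0.35 (SE).

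**Figure D3:**
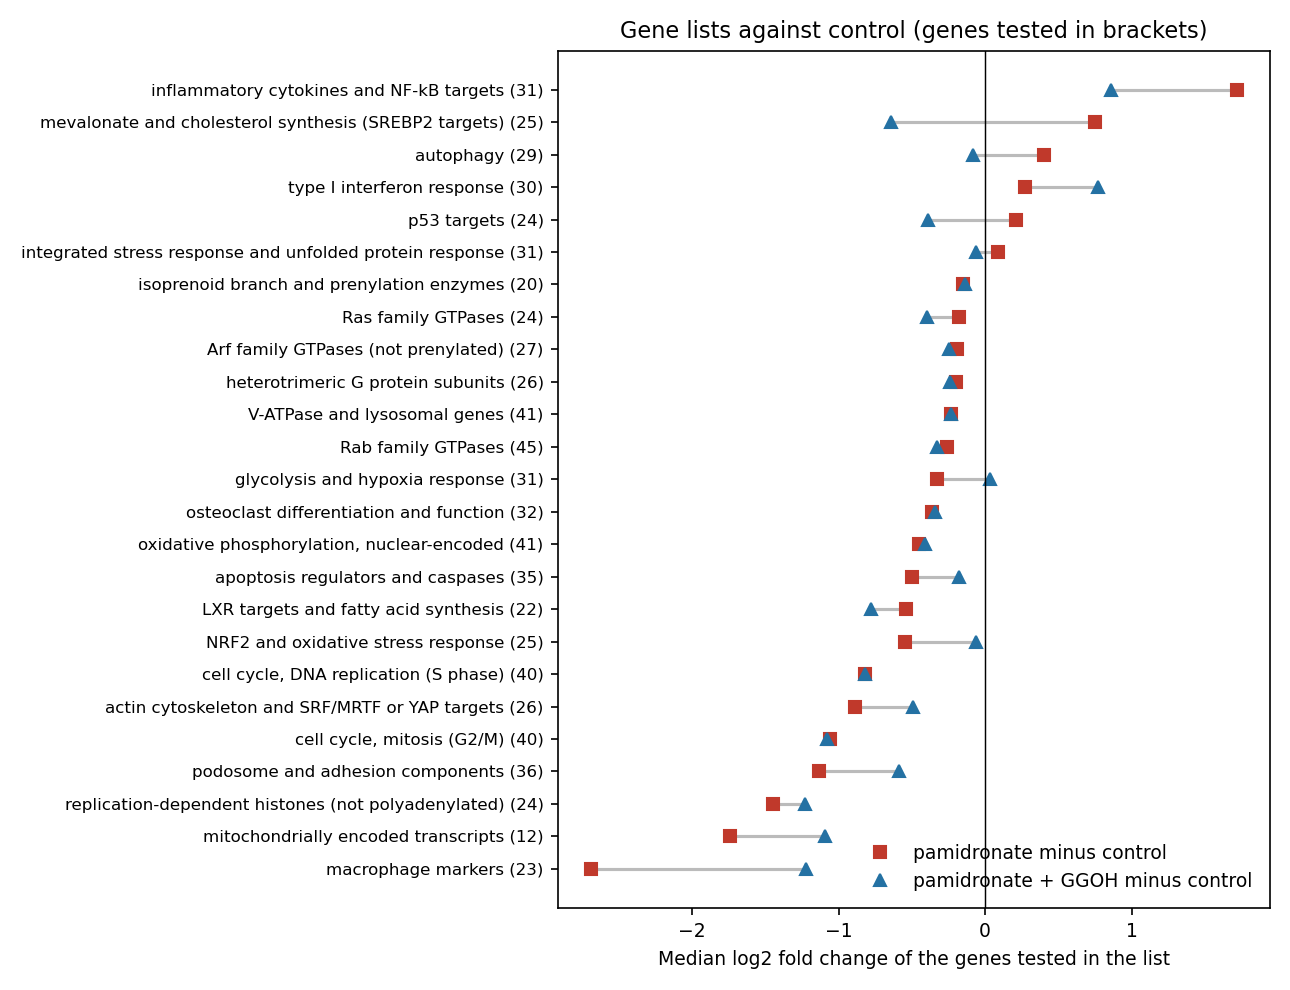
Median log2 fold change against the control of the genes tested in each of 25 lists, with squares for pamidronate and triangles for pamidronate + GGOH. The macrophage markers moved from -2.69 to -1.22 and the sterol genes from 0.75 to -0.64, while with upper-quartile factors the isoprenoid branch medians are 0.04 and 0.06, the pamidronate medians are 0.01 for the Ras list and 0.00 for the Arf list, and the pamidronate + GGOH medians are 0.14 for the integrated stress response, 0.14 for oxidative stress, 0.12 for autophagy and 0.02 for apoptosis.

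Of the 11042 genes called with pamidronate, 6222 (56.3%) were called in the opposite direction when GGOH was added. These included 2970 genes that rose and then fell, such as Hmgcs1, Insig1 and Gdf15, and 3252 that fell and then rose, such as Csf1r, Itga4 and Actb. Independent lists of the same sizes would share 2688 genes in opposite directions. A further 177 genes rose both times and 111 fell both times. Against the control, 6692 genes (60.6%) were called in the same direction with pamidronate and with pamidronate + GGOH, such as Rhoa, Rac1, Cdc42 and Nfatc1, where independent lists would give 2892. Of the genes called in the opposite direction, 2905 were not called against the control, such as Cdkn1a, and 3052 were still called on the pamidronate side. Simulated groups with no difference gave 0.05 genes on average in opposite directions and 0.1 in the same direction against the control. Both pairs of comparisons share libraries, so their fold changes are related by construction. The covariance between pamidronate against control and GGOH against pamidronate was -0.819 across genes, and it was -0.0409 in simulated groups with no difference. The correlation was -0.651, and it was -0.512 in the simulated groups. With the pamidronate group divided into 1 library and 2, so that no library served both comparisons, the covariance was -0.882 to -0.734 over 6 divisions. The genes called in opposite directions then numbered 3546 to 4982, where independent lists would give 1375 to 1936. With the control divided likewise, 4394 to 5602 genes were called in the same direction, where independent lists would give 1682 to 2339, and the covariance was 1.35 to 1.52, against 1.41 with shared libraries. Fewer libraries served each comparison in these divisions, so the numbers of genes are not on the same footing as those above.

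For the genes called with pamidronate, the share of the change on the log2 scale that was undone in a pamidronate + GGOH library had a median of 0.487 ± 0.124 (SD, n = 3), where 0 is the pamidronate mean and 1 the control mean. The 3 libraries gave 0.385, 0.451 and 0.625. The sterol genes passed the control level, at 1.35 ± 0.14 (SD, n = 3). Autophagy genes stood at 0.79 ± 0.13 (SD, n = 3), podosome and adhesion genes at 0.49 ± 0.13 (SD, n = 3) and macrophage markers at 0.47 ± 0.13 (SD, n = 3). Oxidative phosphorylation genes stood at 0.23 ± 0.09 (SD, n = 3) and LXR targets and fatty acid genes at -0.02 ± 0.23 (SD, n = 3). Cell cycle genes differed more between libraries, with replication genes at -0.03, 0.27 and 0.68 and mitosis genes at -0.21, 0.24 and 0.67 in replicates 1, 2 and 3. These values carry no test.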

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

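Leaving out the farthest control and pamidronate + GGOH libraries together, leaving out the genes Gm26917 and Gm42418, upper-quartile factors for genes outside both groups, and dividing a shared group between 2 comparisons, were chosen after seeing the data. Requiring an absolute log2 fold change of at least 1 left 6047 genes for pamidronate against control, 2590 for pamidronate + GGOH against pamidronate and 3079 for pamidronate + GGOH against control. It left 2023 genes changed in opposite directions and 2497 changed the same way against the control. With an estimated correlation, camera called 0, 0 and 0 lists in these comparisons (lowest adjusted p = 0.4, with 1, 2 and 4 at an unadjusted p under 0.05), while fry called 22, 15 and 21. The lower counts follow from the stricter threshold, and the cause of the other differences was not tested. Under the other planned settings the total numbers of genes called stayed within 1.5 times those reported, but the 4157 genes lower with pamidronate + GGOH than in the control became 2600 with upper-quartile factors. DESeq2 called 11122, 7176 and 8344 genes, the replicate block 10980, 7622 and 8275, and an adjusted p under 0.01 left 9314, 5661 and 5998. Leaving out single libraries gave 10207 to 11433, 6590 to 8215 and 6923 to 8932 genes, 5261 to 6402 in opposite directions, 5637 to 7339 the same way, and 12 to 14, 11 to 13 and 16 to 18 lists. Without both farthest libraries the counts were 11539, 7890 and 9211, and without Gm26917 and Gm42418 they were 11038, 7725 and 8364. Named genes were not compared under the minimum fold change, the adjusted p under 0.01, the per-sample files or the divided groups. Of 8061 values of named genes over the other settings, 7860 stayed called or stayed not called, 189 lost their call, 12 gained one and 0 reversed. Lists were compared only with an estimated correlation, fry, RLE factors, a replicate block, a stricter filter and libraries left out. Of 1215 values of lists over these settings, 1104 stayed called or stayed not called, 59 lost their call, 52 gained one and 0 reversed. In simulated data with 200 of 15963 genes changed, 32% of those changed 1.5-fold were recovered. Adjustment is stricter with so few changed genes than in the data, where 11042, 7784 and 8359 genes were called. The simulated share therefore does not give the share of such changes missed in these comparisons. Calcr, the calcitonin receptor, had 0, 0 and 3 counts in the control, pamidronate and pamidronate + GGOH groups, and no difference was detectable for it.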

Other observations

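The tests on mitochondrial and nuclear RNA, on genes within 100 kb upstream of genes that rose from silence, on the position of the pamidronate + GGOH libraries and on genes outside both other groups were chosen after the results were seen. With GGOH, 663 genes were called above both other groups and 718 below both, where independent lists would give 1059 and 980. With upper-quartile factors, 948 were above both and 359 below. Among the lists, Fisher's exact test with adjustment over 27 lists singled out 4. This test treats the genes of a list as independent, so its p-values are too small where they move together. For pamidronate + GGOH against the control, estimated correlations were 0.313 for sterol, 0.176 for LXR, 0.38 for interferon and 0.11 for p53 genes. Camera with an estimated correlation called 0 lists in each comparison. Of 25 sterol synthesis genes, 14 lay outside both groups and all 14 were below (adjusted p = 5.97e-08), and with upper-quartile factors 10 were below (adjusted p = 0.000184). Of 22 LXR targets and fatty acid genes, 10 lay outside and 9 of them below, among them Scd1 (adjusted p = 7.53e-05), and with upper-quartile factors 8 were below (adjusted p = 0.00027). Of 30 interferon response genes, 11 lay outside and all 11 were above, among them Oasl2 (adjusted p = 0.000205), and with upper-quartile factors 13 were above (adjusted p = 6.03e-06). Of 24 p53 targets, 7 lay outside and all 7 were below (adjusted p = 0.0224), but with upper-quartile factors 3 were below and the test was not passed (adjusted p = 0.921).

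Several osteoclast genes were low in the control. The growth notes give RANKL for every sample while the control labels state no treatment, and these values do not settle whether the controls received it. Acp5, tartrate-resistant acid phosphatase, averaged 5.27 ± 1.98 (SD, n = 3) CPM and ranked 9650 of 15963 genes. Ctsk averaged 4.70 ± 1.61 (SD, n = 3) CPM, Dcstamp, needed for cell fusion, 2.56 ± 0.769 (SD, n = 3) CPM and Itgb3 1.53 ± 0.435 (SD, n = 3) CPM. Nfatc1 averaged 134 ± 5.56 (SD, n = 3) CPM, Tnfrsf11a, the RANKL receptor, 129.7 ± 16.8 (SD, n = 3) CPM, and Lyz2, a macrophage lysozyme, ranked 5. Median control levels of the marker lists of other cell types were 0.882 CPM for dendritic cells, 0.106 for epithelial and endothelial cells, 0.0483 for osteoblasts and stroma, 0.0389 for neutrophils, 0.00973 for T and NK cells and 0.00933 for B cells. With pamidronate and with pamidronate + GGOH, the medians were lower for dendritic cells (0.258 and 0.321) and higher for the other lists. They were 0.145 and 0.252 for epithelial and endothelial cells, 0.177 and 0.346 for osteoblasts and stroma, and 0.0835 and 0.204 for neutrophils. For T and NK cells they were 0.165 and 0.181, and for B cells 0.105 and 0.146. The most abundant markers in the control were Spp1, also made by macrophages, at 3945 ± 1478 (SD, n = 3) CPM, Cd74 at 360 ± 35.1 and Ighm at 133 ± 24.5, with Csf3r at 13.5, Vwf at 5.58 and Lck at 4.04 CPM. With pamidronate + GGOH, Il7r reached 25.0 ± 6.59 (SD, n = 3) CPM and Tek 28.4 ± 12.9 (SD, n = 3) CPM. Ighm, Csf3r and Cd74 were lower than in the control, at 30.1, 1.90 and 194 CPM with pamidronate. They averaged 49.6, 6.84 and 302 CPM with pamidronate + GGOH. Spp1 averaged 3597 and 5824 CPM in these groups, and Vwf averaged 8.07 CPM with pamidronate.

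Of 8905 protein-coding genes silent in the control, at under 0.1 CPM, 101 were called higher with pamidronate and reached at least 1 CPM. With GGOH, 97 of these were still called higher than in the control. They were picked for low values in the same control libraries, which favours this. Against pamidronate, 31 were called lower and 10 higher with GGOH. Genomic DNA in the pamidronate libraries is argued against by 1113 olfactory receptor genes, whose mean gain per kilobase was 0.0121 of the median gain of the 101 genes. Reads of overlapping exons of genes at 5 CPM or more cannot account for most of the 101 genes, since 5.94% had such an overlap. Overlaps with introns and with genes at lower levels were not examined, so reads from these stay open. Transcription running on from a gene upstream is argued against as the whole cause, since 40.6% (95% interval 30.9 to 50.8) had an expressed gene on their strand within 50 kb upstream, and 64.4% (54.2 to 73.6) had one within 100 kb when genes at 1 CPM were counted. For the genes with such a neighbour it cannot be told apart, because neighbours were more frequent upstream (odds ratio 4.59) and also downstream (3.14), and the ratio of the 2 was 1.46 with an interval of 0.851 to 2.49. A direct response of these genes to pamidronate may also contribute and was not tested.

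Mitochondrial RNA was lower and Malat1 and Neat1 were higher with pamidronate, with Neat1 at 0.182% of counts in the control and 2.13% with pamidronate. A single smaller mitochondrial share is argued against by the transcripts themselves, since the falls of all 12 spanned 1.64 on the log2 scale, from mt-Co1 to mt-Cytb, while 95% of ranges simulated from their SEs with a common fall were under 1.27. A single larger share for all nuclear RNAs is argued against by Rn7sk, a nuclear RNA, since Malat1 rose by 1.28 (SE 0.19) more. Other nuclear RNAs, named after their values were seen, went both ways. Kcnq1ot1 rose by 1.42 ± 0.11 (SE), while Rmrp and Rpph1 were not called, at 0.08 ± 0.14 and 0.12 ± 0.15 (SE). A larger share of some nuclear RNAs, among them Malat1, Neat1 and Kcnq1ot1, therefore stays open. After leaving out the 11 most abundant genes, 9 of 9 mitochondrial mRNAs still tested remained lower, among them the low-count ones named above. The fall in their fold changes thus does not rest on those abundant genes. TMM factors, which already limit the weight of such genes, were used again, so little change could follow. The share of counts was not tested in this way. A difference in RNA quality or in removal of ribosomal RNA stays open beside a response to pamidronate, since Gm26917, which overlaps ribosomal RNA sequence, held 7.70% of counts in the control, 12.4% with pamidronate and 10.8% with GGOH (exact permutation p = 0.1 for each pair, the smallest possible), while Gm42418, another such gene, held 0.707%, 0.584% and 0.647%.

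On the first principal component the pamidronate + GGOH libraries lay between the other groups, while on the second they lay outside both, at -52.3 to -42.7. A mixture of unaffected and affected cells is argued against as the whole cause, since 4.33% of genes (691) were called outside both groups by at least 0.5 on the log2 scale. The test first counted 1381 genes of any size and was tightened after that result, because scalings shift medians by up to 0.201. Replicate 3 alone did not place the group there, since the median share undone was 0.418 without it. Whether a single mixing share fits both directions cannot be told apart, because the difference between genes that rose and fell was 0.202 with TMM factors and -0.209 with library totals.

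Other splits of the samples were counted for each result. For each comparison, 6 libraries make 10 splits, too few for a share under 0.05. The real splits called 11042, 7784 and 8359 genes and the highest other split 0 in each. For lists, adjusted within a comparison, the real splits called 13, 12 and 17 lists and the highest others 12, 12 and 16, with 1, 2 and 1 of 10 splits as large. Every other split keeps 2 of 3 libraries of a group together. Over 100 splits of the 9 libraries into 3 groups, the real split gave the most genes changed in opposite directions, 6222 (highest other 4634). It also gave the most changed the same way against the control, 6692 (highest other 4270), with 1 of 100 splits as large in each case. This argues against a chance division of the libraries but does not exclude it, since the other splits were a sample. Exchanged names of the real groups were not counted as other splits, so the splits do not test reversal by GGOH itself.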
